A study of Mus musculus with 12 samples.

How the data were processed

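Gene expression was measured with Mouse Gene 1.1 ST arrays from Affymetrix in primary cultures of B lymphoma cells from λ-MYC;B1-8f mice, which carry a MYC transgene and a B-cell receptor (BCR) heavy chain variable region that Cre can delete. Per the labels' protocols, the cultures were transduced with TAT-Cre, a recombinase that enters cells by itself, so that BCR-positive and BCR-negative cells of the same lymphoma grew together. They were kept for 4 days with or without CHIR99021, a small-molecule inhibitor of the kinase GSK3, and were then parted by flow sorting. Total RNA was extracted with an RNeasy kit and labelled with the Ambion WT expression kit, per the labels. Lymphomas 2564, 2646 and 2676 each gave 1 array in each of 4 groups, so that 12 arrays formed groups of 3.

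The deposited values are log2 expression values per probe set, made with RMA in Affymetrix Power Tools, per the submitters' processing notes; versions are not given in the sources used here. The table held 35556 probe sets. The platform annotation listed 23099 of them, 21218 with 1 gene symbol and 1881 with several, and 12457 were not listed and are unnamed here. Of the 21218 probe sets with 1 symbol, 21185 were matched by Entrez identifier to the RefSeq annotation of assembly GRCm38.p6, used for names only, and no symbol changed. The build behind the array's annotation is not given in the sources used here, so no coordinates are printed. Where a gene had several probe sets (1386 genes), the probe set with the highest mean over all arrays stood for it, which left 18820 genes. No pair of arrays held identical values. The array median lay between 4.71 and 4.92 over all probe sets, and arrays of the same lymphoma correlated at r of 0.988 to 0.997 across probe sets. With arrays, their number limits the precision.

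All tests were run with limma 3.58.1 in R 4.3.3 on the deposited log2 values. A linear model with group and lymphoma was fitted over all 12 arrays (6 residual degrees of freedom), followed by eBayes and Benjamini-Hochberg adjustment over the 18820 genes. Genes with an adjusted p under 0.05 are called higher or lower. The pairing comes from the labels, in which each number is an independent lymphoma, and from the design text, in which both populations of a lymphoma shared a culture. Deviations from the group means of arrays of the same lymphoma correlated across genes at r of 0.813 to 0.907 (18 pairs), against -0.574 to -0.248 between lymphomas (36 pairs). Subtracting the group means makes the values between lymphomas negative once those within are positive, so they add no separate evidence. Lymphoma was a block in the model because of the stated pairing. P-values measure how much the changes between groups vary among these 3 lymphomas, pooled over the 4 groups. The block takes out the spread between the lymphomas themselves.

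The 6 comparisons were BCR loss in untreated cultures, BCR loss in CHIR99021 cultures, CHIR99021 in BCR-positive cells, CHIR99021 in BCR-negative cells, the interaction (the BCR-loss effect with CHIR99021 minus that without), and CHIR99021-treated BCR-negative cells against untreated BCR-positive cells. Fixed before the data were examined were 24 gene lists, 5 lists of markers of other cell types, and the rule for named genes. Per comparison the rule took, among called genes with the same sign in all 3 lymphomas, the 10 largest rises and the 10 largest falls (5 for the last 2 comparisons). To these it added the 2 members with the smallest p of each list that was called or had at least 2 called members, and 12 genes that are looked at in every comparison. Of these 12, Gsk3a was not among the genes tested and has no value here. Where no gene passed, it took the 3 smallest p per direction. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. Beside it stand camera with a correlation estimated from the data and fry, which asks whether the members of a list move, on balance, one way.

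The model was tested on 20 sets of simulated data for 18820 genes, with the means, lymphoma differences and residual spread of the arrays. For BCR loss in untreated cultures it recovered on average 75.4% (70% to 79%) of 100 genes changed by 0.5 and 96.9% of 100 changed by 1 on the log2 scale, with 10.2 false calls among 183. For CHIR99021 in BCR-negative cells the mean shares were 74.8% and 96.3%, and for the interaction 45.8% and 88.6%. A shift of 0.3 put into the DNA replication genes was called by camera and no other list was. The simulated genes varied independently, while the correlation estimated from the arrays was 0.66 for that list. The simulation therefore cannot show whether list calls at the preset correlation are sound. Alternatives were no block, lymphoma as a random block, a finer block, only the arrays compared, a filter on dim probe sets (below the 30th percentile of the genes' means), the mean of a gene's probe sets, subtraction of array medians, cyclic loess, eBayes with trend and robust, a minimum change of 1.5-fold, and leaving out each lymphoma or array. Some members of the lists were not analysed here, and each list's result covers its measured members. In the glycolysis list the symbol Gpi1 was matched to Pigq, which the list did not name, so the glycolysis results include Pigq. Probe sets with several symbols or none were left out of the gene tests.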

Results

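The data were 12 arrays of mouse B lymphoma cells, 3 per group, sorted as BCR-positive or BCR-negative after 4 days of co-culture with or without CHIR99021. Lymphoma 2564, 2646 or 2676 gave 1 array to each group. Differences between lymphomas made up 76.7% of the sum of squares over genes and differences between the 4 groups 14.3%, so changes are given within lymphomas, as the mean log2 difference ± its standard error (SE) from limma, n = 3 lymphomas. The mean of the array medians was 4.88 ± 0.054 (SD, n = 3) in untreated BCR-negative cells and 4.82 ± 0.028 in untreated BCR-positive cells. With CHIR99021 it was 4.82 ± 0.041 and 4.77 ± 0.063.

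The deletion was read from Ighv1-72, the variable segment that the B1-8 heavy chain is built from. Its signal was lower in BCR-negative than in BCR-positive cells of every lymphoma and culture. In untreated cultures it fell by 2.11 ± 0.331 (limma, adjusted p = 0.0176), and the BCR-negative signal was 31.8%, 38.2% and 10.3% of the BCR-positive signal in lymphomas 2564, 2646 and 2676. In CHIR99021 cultures it fell by 2.95 ± 0.331 (limma, adjusted p = 0.0498), to 14.97%, 18.2% and 7.92%. Ighv1-72 belongs to a large family of similar segments, and part of its signal can come from relatives. The share left in BCR-negative cells was smaller with CHIR99021 in each lymphoma, and what it came from was not tested. Ighm (-0.02 ± 0.492), Cd79a (0.14 ± 0.0773) and Cd79b (0.01 ± 0.0604), the constant region and the signalling partners of the receptor, were not called for BCR loss in untreated cultures. They lie outside the deleted part and do not check it. The level of Ighm differed between lymphomas, from 4.24 to 4.38 on the 4 arrays of 2564, 4.14 to 4.53 in 2676 and 5.16 to 8.14 in 2646.

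**Figure D1:**
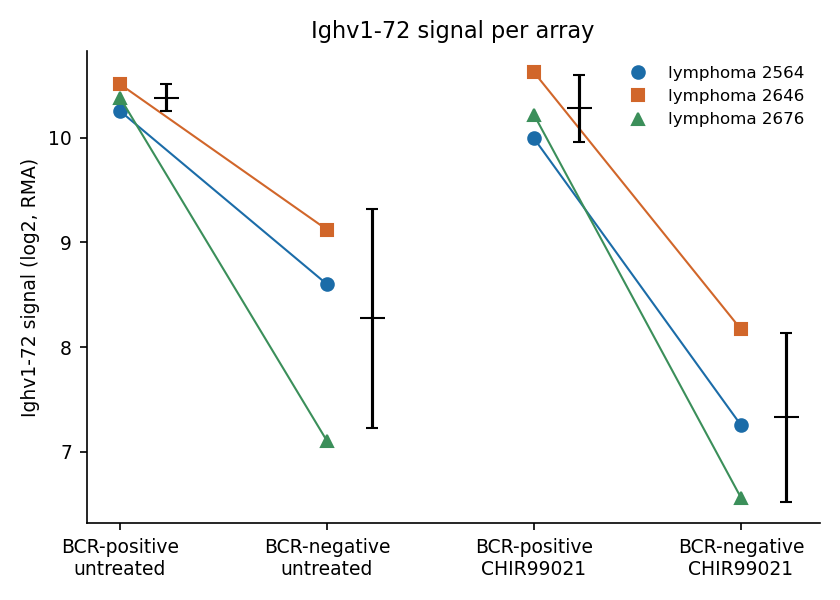
Signal of Ighv1-72 (log2, RMA) on each of the 12 arrays, by group on the x axis; lines join the sorted populations of 1 lymphoma in 1 culture, and black bars are the mean ± SD of 3 arrays. Each BCR-negative array lies below its BCR-positive partner, with the lowest signal (6.56) in lymphoma 2676 with CHIR99021.

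The first comparison asked what changed when lymphoma cells lost the BCR while competing with BCR-positive cells without inhibitor. Of single genes, 8 of 20 NF-κB targets, 5 of 28 early-response genes and 9 of 23 targets of FOXO transcription factors rose in BCR-negative cells, and 7 of 25 DNA replication genes, 4 of 39 MYC targets and 3 of 34 respiration genes fell. As lists these 6 were called at the preset correlation but not with an estimated one (adjusted p = 0.089 to 0.26 with an estimated correlation). Cacna1e, a calcium channel subunit, rose by 2.15 ± 0.180 (4.44-fold) and Tnfaip3, which encodes the NF-κB inhibitor A20, by 2.09 ± 0.180 (4.25-fold). Ccne1, the cyclin that drives entry into S phase, fell by 0.81 ± 0.136, and Cd36, a fatty acid transporter, fell by 1.20 ± 0.263. In all, limma called 359 genes higher and 432 lower of 18820, each with the same sign in all 3 lymphomas.

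Among called genes, the other largest rises were Pinlyp (1.92 ± 0.371), the activation marker Cd69 (1.80 ± 0.398), the AP-1 gene Fosb (1.71 ± 0.365), Prdm1 (1.62 ± 0.293), which encodes the plasma cell regulator Blimp-1, the Notch coactivator Maml2 (1.58 ± 0.181), Nfkbie (1.497 ± 0.106), Tnfsf10 (1.495 ± 0.342), which encodes the death ligand TRAIL, and Mturn (1.48 ± 0.0974). Their adjusted p in limma lay between 0.00046 (Mturn) and 0.0441 (Tnfsf10). Atf3 had a change of 2.15 ± 0.550 but did not pass (limma, adjusted p = 0.0578). The largest falls among called genes after Ighv1-72 were Eml1 (-1.35 ± 0.218), Cd36, Camkv (-0.91 ± 0.214), the protease Ctsh (-0.90 ± 0.214), Pard6g (-0.82 ± 0.150), Anxa9 (-0.82 ± 0.142), Ccne1, Ehd4 (-0.80 ± 0.148) and Zdhhc2 (-0.80 ± 0.181). Of these falls, Ctsh had the highest adjusted p in limma (0.0491).

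Of 23 measured FOXO targets, 9 rose, none fell and 14 did not pass. They included Klf6 (1.38), the PI3K inhibitor Pik3ip1 (1.30 ± 0.128), Irs2 (1.09) and the ubiquitin ligase gene Fbxo32 (0.68 ± 0.0831). The list's median was 0.57 (camera, adjusted p = 3.6e-15, and adjusted p = 0.089 with an estimated correlation), and 17 members were higher when adjusted over the list alone. Of 20 NF-κB targets 8 rose and none fell, among them Nfkbie, Tnfaip3, Nfkbia (1.12) and Nfkb2 (0.91). The list's median was 0.32 (camera, adjusted p = 9.1e-07, and adjusted p = 0.089 with an estimated correlation), with 10 members higher adjusted over the list alone. Of 28 early-response genes that BCR signalling is known to induce, 5 rose (Cd69, Fosb, Dusp6 by 1.34, Egr1 by 1.04 ± 0.208 and Ier3 by 0.80 ± 0.104), with a median of 0.57 (camera, adjusted p = 1.1e-07, and adjusted p = 0.23 with an estimated correlation) and 12 adjusted over the list alone. The median of that list was 0.49 in lymphoma 2564, 0.80 in 2646 and 0.07 in 2676.

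All 25 measured DNA replication genes had a negative change and 7 fell, with Ccne1, the origin recognition gene Orc1 (-0.71 ± 0.135), Gins1 (-0.56), Mcm10 (-0.50), Chaf1b, Clspn and Mcm2 (-0.33). The median was -0.33 (camera, adjusted p = 1.5e-14, and adjusted p = 0.23 with an estimated correlation), with 24 lower adjusted over the list alone. All 39 nucleolar and growth targets of MYC had a negative change and 4 fell, among them the ribosome assembly genes Wdr74 (-0.46 ± 0.0840) and Mrto4 (-0.44 ± 0.0798). Their median was -0.22 (camera, adjusted p = 2.1e-13, and adjusted p = 0.26 with an estimated correlation), with 24 lower adjusted over the list alone. Of 34 oxidative phosphorylation genes all were negative and 3 fell, Ndufa4 (-0.39 ± 0.0929), Ndufv1 (-0.37 ± 0.0859) and Cox5b (-0.22). The list's median was -0.16 (camera, adjusted p = 1.8e-10, and adjusted p = 0.23 with an estimated correlation), with 14 adjusted over the list alone. In nucleotide synthesis (median -0.28), Rrm2 (-0.41 ± 0.0750) and Gmps (-0.29) fell and Ctps2 rose (0.40 ± 0.0619), with 18 lower and 1 higher adjusted over the list alone (camera, adjusted p = 2.7e-09, and adjusted p = 0.23 with an estimated correlation). In cholesterol synthesis (median -0.27), Idi1 fell (-0.32 ± 0.0758), Sqle did not pass (-0.32 ± 0.0791), and 11 were lower and 1 higher adjusted over the list alone (camera, adjusted p = 4.3e-06, and adjusted p = 0.32 with an estimated correlation). No mitosis gene was called, Cdca8 (-0.30 ± 0.0788) and Aurka (-0.28 ± 0.0916) included, while the list's median was -0.13 (camera, adjusted p = 0.00019, and adjusted p = 0.45 with an estimated correlation).

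Adhesion and homing receptors were called higher (median 0.08; camera, adjusted p = 0.0040, and adjusted p = 0.18 with an estimated correlation), with the sphingosine receptor S1pr4 (1.04 ± 0.0985) and the chemokine receptor Cxcr4 (0.51 ± 0.116). Weaker calls were those of p53 targets (median 0.09), with Btg2 (1.06 ± 0.248) and Trp53inp1 (0.73 ± 0.145), of Wnt targets (median 0.06), with Sox4 (0.90 ± 0.155) and Tcf7l2 (0.74 ± 0.135), and of lysosome genes (median 0.09), where Mcoln1 (0.30 ± 0.0731) and Psap (0.28 ± 0.0763) did not pass. Their adjusted p in camera were 0.042, 0.047 and 0.025, and adjusted p = 0.23, 0.26 and 0.45 with an estimated correlation. The lysosome median was -0.13 in lymphoma 2564, 0.22 in 2646 and 0.12 in 2676. The other 11 lists were not called, although some of their members passed. The adaptor Blnk (0.63 ± 0.0962) and Vav2 (0.31 ± 0.0707) rose in the list of BCR components (median 0.01), while Syk (0.22 ± 0.0688) did not pass. Beside Prdm1, the co-chaperone gene Dnajb9 (0.88) and Herpud1 (0.40) rose and Creld2 (-0.46 ± 0.0881) fell among plasma cell genes (median -0.10, mean 0.07). Among stress genes Gadd45a (0.88 ± 0.167) and Jun (0.96 ± 0.216) rose and the chaperone gene Hsph1 (-0.51) fell, and the median was -0.08 while the mean was 0.21. The amino acid response enzymes Mthfd2 (-0.48 ± 0.111) and Psat1 (-0.42 ± 0.0932) fell (list median -0.07). The death gene Bmf rose by 1.41 (BCL2 family, median 0.07), H2-K1 by 0.44 (antigen presentation, median 0.03) and Slc11a2 by 0.53 (iron, median -0.01), while Ifi35 fell by 0.32 (interferon response, median -0.01). With fry, which tests whether members move one way, 8 of the 24 lists were called, those of FOXO, NF-κB, early-response, MYC, nucleotide, respiration, DNA replication and homing genes. Glycolysis (median -0.08), hypoxia (median 0.08) and germinal centre genes (median 0.00) had no called member. Gsk3b (0.08 ± 0.0527), Ctnnb1, Axin2, Lef1, Igkc and the mouse Myc gene (0.03 ± 0.0551) did not pass.

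The number of genes rested on the pairing and on a few arrays. All 791 called genes had 1 sign in the 3 lymphomas, so leaving out a lymphoma or changing the block could not reverse them, and kept signs are no evidence of stability. Without the lymphoma block limma called 5 genes (1232 at an unadjusted p under 0.05), with lymphoma as a random block 75, and in a fit of only the 6 arrays compared 0 (3527 at an unadjusted p under 0.05). Without lymphoma 2646 none was called (2147 at an unadjusted p under 0.05) and without 2676 there were 22. Of single arrays, the untreated BCR-positive ones of 2564, 2646 and 2676 gave 414, 47 and 45 genes when left out, the untreated BCR-negative ones 1204, 88 and 363, the CHIR99021-treated BCR-positive ones of 2646 and 2676 gave 445 and 527, and the treated BCR-negative one of 2646 gave 327. The split moved with the scaling, from 359 higher and 432 lower to 288 and 1013 after subtraction of array medians and to 389 and 261 after cyclic loess. The calls of mitosis, p53 and lysosome genes ended without lymphoma 2646 (camera, adjusted p = 0.078, 0.34 and 0.55), that of lysosome genes also without 2676 (adjusted p = 0.052), and that of Wnt targets without 2564 or 2676 (adjusted p = 0.16 and 0.056) and after cyclic loess (adjusted p = 0.073). The Wnt and p53 calls also ended with the finer block (adjusted p = 0.062 and 0.095), with the dim filter (adjusted p = 0.14 and 0.12) and with only the 6 arrays (adjusted p = 0.074 and 0.069).

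**Figure D2:**
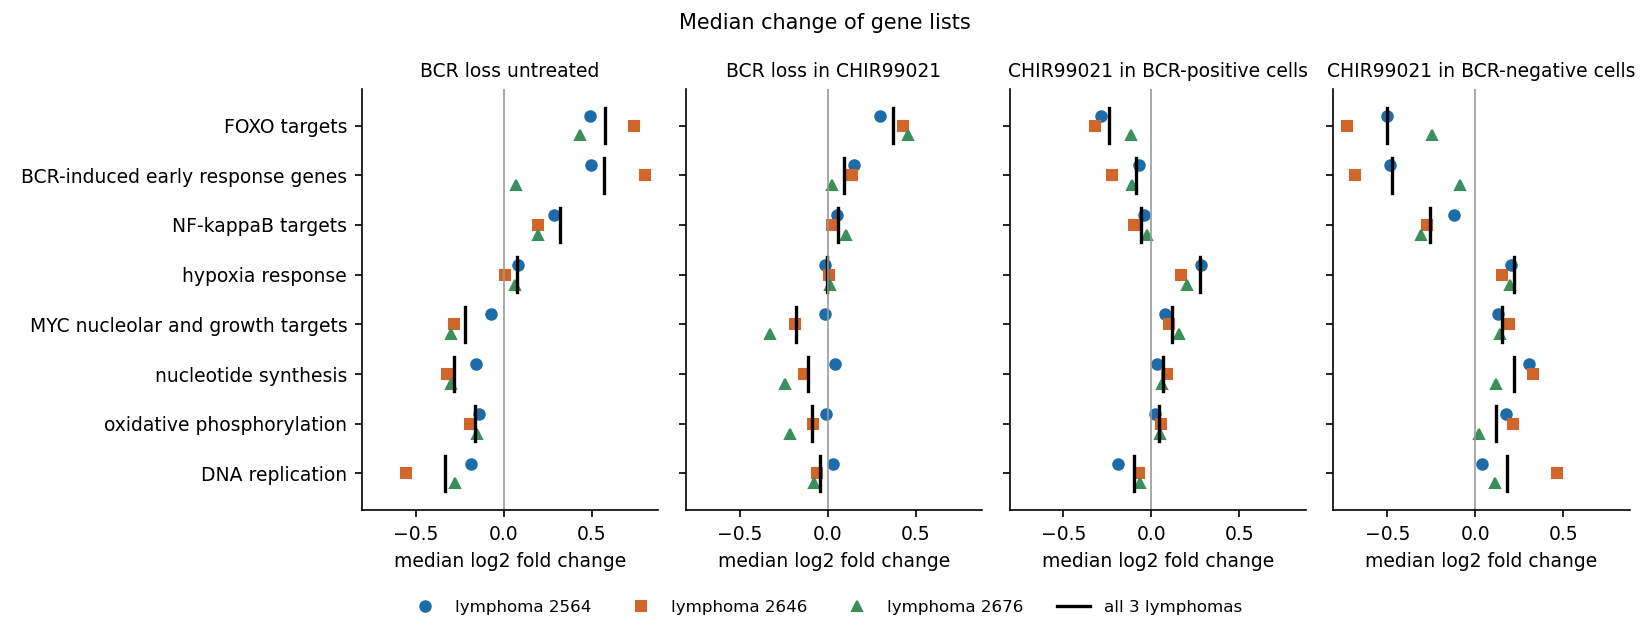
Median log2 fold change of 8 gene lists (y axis) in 4 comparisons (panels); coloured symbols are the median over a list's genes in 1 lymphoma and black bars the median of the fitted changes over all 3 lymphomas. FOXO targets lie at 0.57 for BCR loss in untreated cultures and at -0.50 for CHIR99021 in BCR-negative cells, and DNA replication genes at -0.33 and 0.18.

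The second comparison asked what BCR loss did while GSK3 was inhibited in both populations. Mturn (0.84 ± 0.0974) and the transcription factor gene Foxc1 (0.42 ± 0.0489) were higher and Ighv1-72 lower in BCR-negative cells, and these were the 3 genes called (limma, adjusted p = 0.0498 for each). At an unadjusted p under 0.05 there were 1628 genes. FOXO targets were called higher (median 0.37, all 23 members positive; camera, adjusted p = 8.1e-13, and adjusted p = 0.27 with an estimated correlation), with 10 members higher adjusted over the list alone. Their smallest-p members Sesn3 (0.43 ± 0.0697) and Pik3ip1 (0.60 ± 0.128) did not pass alone over all genes. Early-response genes had a median of 0.09 (camera, adjusted p = 0.0073, and adjusted p = 0.52 with an estimated correlation), with Fos at 0.85 ± 0.315, Rgs2 at 0.44 ± 0.157 and Egr1 at 0.40 ± 0.208.

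Of the MYC targets, 38 of 39 were negative (median -0.18; camera, adjusted p = 2.2e-15, and adjusted p = 0.41 with an estimated correlation), with the smallest p for Rrp12 (-0.38 ± 0.0878) and Mrto4 (-0.29 ± 0.0798). The MYC median was -0.02 in lymphoma 2564, -0.18 in 2646 and -0.33 in 2676. The other lists called lower were oxidative phosphorylation (median -0.09, all 34 negative, with Cyc1 at -0.17 and Ndufb3 at -0.16), cholesterol synthesis (median -0.17, all 20 negative, with Mvd at -0.36 and Mvk at -0.23), the amino acid response (median -0.15, with Asns at -0.40 and Psat1 at -0.26), nucleotide synthesis (median -0.11, with Dhodh at -0.24 and, of opposite sign, Ctps2 at 0.31) and glycolysis (median -0.07, with Pfkm at -0.25 and Pfkl at -0.20). Each of these 5 had an adjusted p of 0.41 with an estimated correlation, and no member passed over all genes. In lymphoma 2564 the medians of the amino acid response (0.02) and nucleotide synthesis (0.04) were positive. DNA replication genes (median -0.04) were not called here. Syk (0.19 ± 0.0688), Cd79a, Cd79b, Igkc, Ighm (-0.94 ± 0.492), Gsk3b, Ctnnb1, Axin2, Lef1 and Myc did not pass. The mean for Ighm rested on lymphoma 2646, with a signal of 8.14 in BCR-positive and 5.16 in BCR-negative cells. In the same order it was 4.25 and 4.24 in 2564 and 4.14 and 4.31 in 2676. The 3 gene calls lay at the threshold. Without the block limma called 0 genes (415 at an unadjusted p under 0.05), and it called 0 with a random or finer block, after the dim filter, after either rescaling and with trend and robust (1067 to 1896 at an unadjusted p under 0.05). Without lymphoma 2564, 2646 and 2676 there were 4 (none of the 3), 0 and 1 genes, and leaving out any single array gave 0, except the untreated BCR-negative array of 2676, which gave 2. Nucleotide synthesis and glycolysis were not called without lymphoma 2676 (camera, adjusted p = 0.058 for both) nor early-response genes without 2564 (adjusted p = 0.057) or with the dim filter (adjusted p = 0.063).

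The third comparison asked how CHIR99021 changed BCR-positive cells. Reep6, an endoplasmic reticulum shaping gene, rose by 0.92 ± 0.118, and it was the only gene called higher. Of 13 genes called lower the 10 largest falls were Klhl24 (-1.90 ± 0.258), Crebrf (-1.46 ± 0.181), a regulator of the unfolded protein response, Mturn (-1.16 ± 0.0974), Fbxl20 (-1.04 ± 0.141), Pik3cg (-1.04 ± 0.136), which encodes a PI3K subunit, the linker histone gene H1f10 (-0.99), Frat1 (-0.79 ± 0.0991), which encodes a GSK3-binding protein, the nuclear envelope gene Sun2 (-0.69 ± 0.0857), Fbxo32 (-0.65 ± 0.0831) and Cacna2d4 (-0.56 ± 0.0785). The adjusted p in limma ran from 0.00825 (Mturn) to 0.0488 (Cacna2d4). At an unadjusted p under 0.05 there were 1891 genes.

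FOXO targets were called lower (median -0.24, 21 of 23 negative; camera, adjusted p = 1.5e-08, and adjusted p = 0.31 with an estimated correlation), with Fbxo32 called and Ccng2 at -1.08 ± 0.172, and 6 lower adjusted over the list alone. Hypoxia genes were called higher (median 0.28; camera, adjusted p = 1.4e-05, and adjusted p = 0.057 with an estimated correlation), with Ero1a at 0.41 ± 0.0810 and Vegfa at 0.35 ± 0.0763, and 9 higher adjusted over the list alone. Also called higher were the amino acid response (median 0.18, Sesn2 at 0.81 ± 0.218 and Slc7a5 at 0.27), MYC targets (median 0.11, Noc4l at 0.22 and Rrp9 at 0.31), glycolysis (median 0.10, Pfkl at 0.29 and Pfkp at 0.35), lysosome genes (median 0.11, Lamp1 at 0.32 and Neu1 at 0.37) and oxidative phosphorylation (median 0.04, Cox4i1 at 0.20 and Ndufb8 at 0.21). Called lower were mitosis genes (median -0.10, Nek2 at -0.36 and Cenpf at -0.44), DNA replication genes (median -0.10, Mcm7 at -0.25 and Rfc3 at -0.29), BCR components (median -0.11, Syk at -0.35 ± 0.0688 and Cd79b at -0.30 ± 0.0604) and early-response genes (median -0.09, Egr1 at -0.63 ± 0.208 and Nr4a2 at -0.53). None of these members passed alone, and the 9 lists had an adjusted p of 0.39 to 0.53 with an estimated correlation. Wnt targets were not called (median 0.02), and neither were Axin2 (0.09 ± 0.104) or Lef1 (-0.02 ± 0.0734), which β-catenin is known to induce, nor Ctnnb1, Gsk3b, Cd79a, Igkc, Ighm or Myc (-0.17 ± 0.0551). Axin2 and Lef1 had low signals, 5.10 and 4.37 in untreated BCR-positive cells, against a median of 5.13 for all genes. The Wnt targets Znrf3 (0.41 ± 0.0613) and Fzd7 (0.59 ± 0.119) were higher adjusted over the list alone, and no member was lower. Without the block limma called 0 genes (411 at an unadjusted p under 0.05) and camera no longer called BCR components (adjusted p = 0.053), and a fit of only the 6 arrays compared called 109. None of the 14 calls was left without any 1 lymphoma, although 1 other gene was called without 2564. The count fell to 0 without any 1 of the untreated or treated BCR-positive arrays of 2564 or 2676 or the treated one of 2646, and to 6 without the untreated one of 2646. They were 2 without the treated BCR-negative array of 2646, and 38, 35 and 3 without the untreated BCR-negative array of 2564, 2646 and 2676. After subtraction of array medians 2 genes were called, both lower, and after cyclic loess 1 higher and 8 lower, and the early-response and respiration calls ended without lymphoma 2646 (camera, adjusted p = 0.21 and 0.057).

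The fourth comparison asked how CHIR99021 changed BCR-negative cells, the population that the design text describes as being lost from untreated co-cultures. Of single genes, 6 of 20 NF-κB targets, 4 of 28 early-response genes and 7 of 23 FOXO targets fell, and as lists these 3 were called at the preset correlation and with fry but not with an estimated correlation (adjusted p = 0.11 to 0.18 with an estimated correlation). Among called genes Cd36 and Reep6 had the largest rises, and Cdkn1a (1.46), Adm (1.23), Hmox1 (1.16) and Pld4 (1.08) had larger changes than Reep6 but did not pass (limma, adjusted p = 0.0679, 0.0737, 0.129 and 0.0825). The largest falls were those of Crebrf (-1.88 ± 0.181), Cd69 (-1.87 ± 0.398), Mturn (-1.80 ± 0.0974), Klhl24 (-1.79 ± 0.258) and Tnfaip3 (-1.73 ± 0.180). Cd36 rose by 1.52 ± 0.263 (2.88-fold) and Reep6 by 1.06 ± 0.118. In all limma called 360 genes higher and 332 lower, each with the same sign in all 3 lymphomas.

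The other large falls were the kinase gene Pim1 (-1.66 ± 0.160), Pinlyp (-1.64 ± 0.371), the recombinase gene Rag2 (-1.63 ± 0.347), Cacna1e (-1.58 ± 0.180) and the kinase gene Dyrk1b (-1.48 ± 0.226). The other large rises were Angptl4 (0.82 ± 0.172), an inhibitor of lipoprotein lipase, Kbtbd8 (0.80 ± 0.121), the Fanconi anaemia gene Fancb (0.80 ± 0.122), Abi2 (0.79 ± 0.122), Tspan4 (0.79 ± 0.111), Mpzl1 (0.77 ± 0.151), Gemin6 (0.75 ± 0.116) and Cyth4 (0.75 ± 0.102). Across these genes the highest adjusted p in limma was 0.0447 (Pinlyp).

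Of 23 FOXO targets all were negative and 7 fell, among them Rag2, Pik3ip1 (-1.17 ± 0.128), Ccng2 (-1.03) and Fbxo32 (-0.97 ± 0.0831), with a median of -0.50 (camera, adjusted p = 6.6e-14, and adjusted p = 0.11 with an estimated correlation) and 14 lower adjusted over the list alone. Of 20 NF-κB targets 6 fell, with Tnfaip3, Nfkbie (-1.25 ± 0.106), Nfkbia (-0.91) and Nfkb2 (-0.72), a median of -0.26 (camera, adjusted p = 3.7e-06, and adjusted p = 0.11 with an estimated correlation) and 10 lower adjusted over the list alone. Of 28 early-response genes 4 fell, Cd69, Egr1 (-1.27 ± 0.208), Dusp2 (-1.004 ± 0.153) and Nr4a2 (-0.72), with a median of -0.48 (camera, adjusted p = 4.1e-08, and adjusted p = 0.18 with an estimated correlation) and 14 lower and 1 higher adjusted over the list alone. The median of that list was -0.48 in lymphoma 2564, -0.68 in 2646 and -0.09 in 2676. Among BCR components (median -0.17) the kinases Prkcb (-0.87) and Syk (-0.39 ± 0.0688) and the receptor partner Cd79b (-0.33 ± 0.0604) fell, with 7 lower adjusted over the list alone. Antigen presentation genes had a median of -0.21, with H2-K1 (-0.62 ± 0.104), Tapbp (-0.43) and Tap2 (-0.24 ± 0.0546) lower, and homing receptors a median of -0.07, with S1pr4 (-0.65 ± 0.0985) and Cd44 (-0.24 ± 0.0541) lower. These 3 lists were called lower (camera, adjusted p = 2.4e-05, 0.0020 and 0.013), with an adjusted p of 0.18 for each with an estimated correlation.

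MYC targets were called higher (median 0.15, 37 of 39 positive; camera, adjusted p = 4.1e-08, and adjusted p = 0.39 with an estimated correlation), with Nip7 (0.42), Mrto4 (0.37 ± 0.0798), Wdr74 (0.36) and Hspd1 (0.30 ± 0.0641) past the threshold and 9 higher adjusted over the list alone. DNA replication genes were called higher (median 0.18; camera, adjusted p = 2.5e-06, and adjusted p = 0.39 with an estimated correlation), with Orc1 (0.65 ± 0.135) and Ccne1 (0.62 ± 0.136) called and 10 higher adjusted over the list alone. The median was 0.04 in lymphoma 2564, 0.47 in 2646 and 0.11 in 2676, and that of cholesterol synthesis was 0.24, 0.30 and -0.09. Nucleotide synthesis (median 0.22) held rises of Impdh1 (0.34 ± 0.0701) and Gmps (0.31) and a fall of Ctps2 (-0.31 ± 0.0619), hypoxia genes (median 0.22) rises of Ero1a (0.44 ± 0.0810), Higd1a (0.43 ± 0.0761) and Egln1 (0.30), the amino acid response (median 0.14) a rise of Mthfd2 (0.54 ± 0.111), and cholesterol synthesis (median 0.17) a rise of Sqle (0.34 ± 0.0791) and a fall of Insig1 (-0.35 ± 0.0754). Oxidative phosphorylation (median 0.12, all 34 positive, Ndufa4 at 0.38) and glycolysis (median 0.15, Hk2 at 0.45) had no called member. These 6 lists were called higher, with an adjusted p of 0.18 to 0.55 with an estimated correlation. Adjusted over the list alone, 7 nucleotide genes were higher and 1 lower, 9 hypoxia genes higher and 4 lower, 4 cholesterol genes higher and 1 lower, and 5 antigen presentation genes lower and 1 higher. Of genes in lists that were not called, Trp53inp1 (-0.98 ± 0.145), Bmf (-1.30), Dnajb9 (-0.93 ± 0.201), Herpud1 (-0.46 ± 0.0853), Gadd45a (-0.71 ± 0.167) and Tcf7l2 (-0.66 ± 0.135) fell, and Hsph1 (0.67 ± 0.120), Ccng1 (0.31 ± 0.0697) and the Wnt feedback gene Znrf3 (0.28 ± 0.0613) rose. Axin2 (0.08 ± 0.104), Lef1 (-0.01 ± 0.0734), Ctnnb1, Gsk3b, Cd79a, Igkc, Ighm and Myc (-0.16 ± 0.0551) did not pass.

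As for BCR loss, the count rested on the pairing, and the signs of the 692 genes could not reverse in those fits either. Without the block limma called 3 genes (1070 at an unadjusted p under 0.05), with a random block 81, and in a fit of only the 6 arrays compared 29. Without lymphoma 2564, 2646 and 2676 there were 113, 0 and 175 genes. Without the CHIR99021-treated BCR-negative array of 2564 or 2646 there were 57 and 51, without the untreated one of 2646 there were 111, and without the treated BCR-positive arrays of 2646 and 2676 or the untreated one of 2676 there were 432, 426 and 390. After subtraction of array medians 836 were higher and 253 lower, and after cyclic loess 237 and 354. The calls of glycolysis, hypoxia, cholesterol and antigen presentation genes ended without the block (camera, adjusted p = 0.053, 0.31, 0.34 and 0.17), the hypoxia call also with the dim filter (adjusted p = 0.070), after subtraction of array medians (adjusted p = 0.11) and without lymphoma 2564 (adjusted p = 0.082), and the cholesterol call also with the dim filter (adjusted p = 0.055), after cyclic loess (adjusted p = 0.072) and without 2564 or 2646 (adjusted p = 0.27 and 0.23).

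The interaction asked whether the effect of BCR loss differed between the cultures. limma called 0 genes, with a smallest adjusted p of 0.276 and 990 genes at an unadjusted p under 0.05, and 2 genes without the untreated BCR-negative array of 2676. The smallest p belonged to Lima1 (-1.10 ± 0.137), Nfkbie (-0.93 ± 0.150) and Tnfaip3 (-1.55 ± 0.255) among negative values and to the chromatin remodelling gene Smarca5 (0.40 ± 0.0793), Pdhx (0.39 ± 0.0792) and the replication factor gene Rfc1 (0.37 ± 0.0764) among positive ones, none of them called. As lists, NF-κB targets (median -0.20), FOXO targets (median -0.23) and early-response genes (median -0.20) were called toward lower values with CHIR99021, and DNA replication genes (median 0.33, all 25 positive) and mitosis genes (median 0.21) toward higher values. Among them stood Ier3 (-0.59 ± 0.147), Cd69 (-1.67 ± 0.563), Pik3ip1 (-0.70 ± 0.181), Fbxo32 (-0.32 ± 0.118), Clspn (0.56 ± 0.127), Rfc3 (0.45 ± 0.135), Cdca8 (0.28) and Prc1 (0.24). These 5 lists had adjusted p of 1.5e-07, 5.0e-05, 5.0e-05, 3.5e-15 and 1.8e-08 in camera and adjusted p = 0.080, 0.34, 0.34, 0.34 and 0.34 with an estimated correlation. The other 6 lists called were nucleotide synthesis (median 0.12, Rrm2 at 0.30 and Gmps at 0.24), oxidative phosphorylation (median 0.07, Ndufa4 at 0.33 and Ndufs1 at 0.19), antigen presentation (median -0.14, H2-K1 at -0.51 and Tap2 at -0.27), lysosome genes (median -0.11, Neu1 at -0.31 and, of opposite sign, Atp6v1h at 0.24), Wnt targets (median -0.10, Tcf7l2 at -0.43 and Ctla4 at -0.19) and homing receptors (median -0.06, S1pr4 at -0.70 and Ccr6 at -0.18), with adjusted p of 0.20 to 0.59 with an estimated correlation. Ctla4 and Ccr6 were among the dim genes. Without the block the last 4 of these lists were not called, which left 7 (camera, adjusted p = 0.19, 0.065, 0.080 and 0.11). Respiration was not called without 2564 or 2646, lysosome genes without 2646 or 2676, homing receptors without 2646, and Wnt targets without 2564 or 2676 (camera, adjusted p from 0.051 to 0.57).

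The last comparison set CHIR99021-treated BCR-negative cells beside untreated BCR-positive cells. Ighv1-72 was lower (-3.05 ± 0.331), as were Frat1 (-0.99 ± 0.0991) and the zinc finger gene Hivep2 (-0.88 ± 0.101), with adjusted p of 0.0400, 0.0400 and 0.0432 in limma. No other gene was called, and 1644 had an unadjusted p under 0.05. FOXO targets (median 0.07), NF-κB targets (median 0.09) and early-response genes (median 0.01, Egr1 at -0.23 ± 0.208) were not called. Hypoxia genes were called higher (median 0.27; camera, adjusted p = 5.3e-06, and adjusted p = 0.037 with an estimated correlation), with Vegfa at 0.35 ± 0.0763 and Ero1a at 0.34 ± 0.0810, and 9 higher adjusted over the list alone.

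Lysosome genes (median 0.14, Psap at 0.37 and Neu1 at 0.34) and p53 targets (median 0.10, Zmat3 at 0.57 and Polk at 0.25) were also called higher. DNA replication (median -0.16, Mcm3 at -0.25 and Mcm7 at -0.23), BCR components (median -0.12, Cd79b at -0.32 ± 0.0604 and Vav2 at 0.26), cholesterol synthesis (median -0.07, Fdft1 at -0.29 and Mvk at -0.24), MYC targets (median -0.05, Bysl at -0.22 and Fbl at -0.18), mitosis (median -0.04, Nek2 at -0.33 and Cdc20 at -0.26), oxidative phosphorylation (median -0.03, Ndufv1 at -0.24 and Ndufb3 at -0.18) and germinal centre genes (median -0.06, Neil1 at -0.39 and Spib at -0.52) were called lower. No member passed, and these 9 lists had adjusted p of 0.29 to 0.62 with an estimated correlation. Syk (-0.16 ± 0.0688), Gsk3b, Ctnnb1, Axin2, Lef1, Igkc, Ighm, Cd79a and Myc did not pass. The 3 gene calls went to 0 without the block, with a random block, in a fit of only the 6 arrays, without lymphoma 2646 or without any of the untreated BCR-positive arrays of 2564 or 2676, the treated BCR-negative ones of 2646 or 2676 or the treated BCR-positive ones of 2564 or 2646. There were 7, none of the 3, without lymphoma 2564, 9 and 5 without the untreated BCR-negative array of 2564 and 2646, and 5 without the treated BCR-positive array of 2676. Without the block cholesterol, p53 and germinal centre genes were not called (camera, adjusted p = 0.072, 0.15 and 0.081), and without lymphoma 2676 the median of oxidative phosphorylation was 0.01 and MYC, cholesterol, mitosis and germinal centre genes were not called (adjusted p = 0.49, 0.30, 0.058 and 0.058). Without 2646 MYC, cholesterol, p53 and germinal centre genes were not called (camera, adjusted p = 0.20, 0.052, 0.095 and 0.059), nor mitosis and germinal centre genes without 2564 (adjusted p = 0.065 and 0.095).

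Across genes the BCR-loss effects in the 2 cultures, which share no array, correlated at Pearson's r = 0.691 and Spearman's rho = 0.523, with a slope of 0.466 for the CHIR99021 culture on the untreated one. Of 359 genes called higher in untreated cultures, 345 had a positive sign with CHIR99021 and the median change went from 0.54 to 0.27. Of 432 called lower, 401 had a negative sign and the median went from -0.39 to -0.13. These genes were chosen by their values in untreated cultures, which by itself makes the values in the other culture smaller, and no gene was called for the interaction. Mturn and Ighv1-72 were called in both cultures, 1 gene in each direction, where independent lists would share 0.0382 and 0.0230. Ighv1-72 is the deleted segment itself, so its fall in both cultures was set by the design and is no evidence of a shared response. The CHIR99021 effects in the 2 populations correlated at r = 0.655 (rho = 0.464), with 655 of the 692 genes called in BCR-negative cells having the same sign in BCR-positive cells. Reep6 rose in both, and 12 genes fell in both, against 0.0191 and 0.229 for independent lists. Both populations of a lymphoma shared a culture, so any other difference between its treated and untreated cultures enters both effects. That alone can raise this agreement, and the 2 effects are not independent replication. Genes are not independent replicates. Per lymphoma (2564, 2646 and 2676), r was 0.222, 0.575 and 0.636 for BCR loss and 0.561, 0.448 and 0.394 for CHIR99021.

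For most genes called for BCR loss, the effect of CHIR99021 had the opposite sign in both populations. Of the 359 genes called higher for BCR loss in untreated cultures the median change with CHIR99021 was -0.41 in BCR-negative and -0.12 in BCR-positive cells, and of the 432 called lower it was 0.32 and 0.05. In BCR-positive cells 266 of the 359 and 293 of the 432 had the opposite sign. The values in BCR-negative cells share arrays with the choice of these genes, as do those in BCR-positive cells in the other direction, and no gene was called for the interaction. In BCR-negative cells, Tnfaip3, Nfkbie, Cd69, Cacna1e, Mturn and Pik3ip1, which rose with BCR loss, fell with CHIR99021. Cd36, Ccne1, Orc1 and Mrto4, which fell with BCR loss, rose with CHIR99021 there. Of these genes only Mturn was also called for CHIR99021 in BCR-positive cells. For CHIR99021 in BCR-negative cells, 164 of the 359 genes called higher for BCR loss were called lower. Of the 432 called lower 178 were called higher. Independent lists would share 6.33 and 8.26. The 2 effects share arrays, which raises the overlap by itself, so these 2 values are not what would be found without a common effect. No gene was called in the same direction in both. Across genes the CHIR99021 effect in BCR-negative cells and the reversed BCR-loss effect correlated at r = 0.7497 (rho = 0.691), with 74.4% of signs the same. The untreated BCR-negative arrays enter both effects, which alone gave a mean r of 0.497 (0.463 to 0.533 over 100 simulations) and 66.6% of signs. The simulated genes varied independently, so that range can be too narrow for genes that vary together. The covariance was 0.0280 against a mean of 0.00536 in the simulations. With the effects taken from different lymphomas, which share no array, r lay between 0.148 and 0.477 over 6 ordered pairs, and the median covariance was 0.0233.

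**Figure D3:**
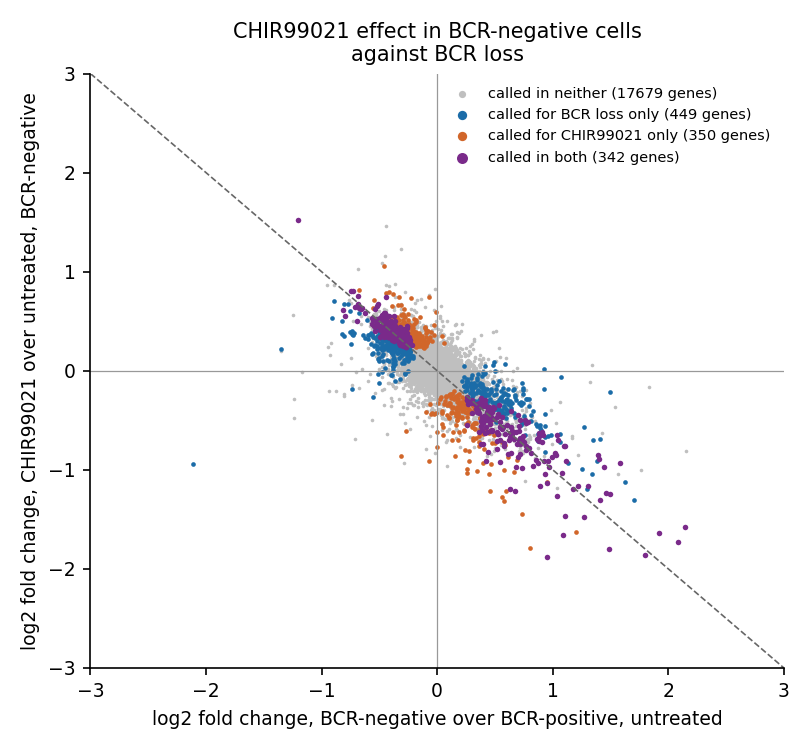
Each point is 1 of 18820 genes, with the log2 fold change for BCR loss in untreated cultures on the x axis and for CHIR99021 in BCR-negative cells on the y axis; colours show where a gene was called and the dashed line marks equal and opposite changes. All 342 genes called in both lie at the upper left or lower right, and Ighv1-72 lies farthest to the left (x = -2.11).

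Markers of other cell types were dim and no list was called in any comparison. The median level over all arrays was 4.00 for T-cell, 4.27 for macrophage and neutrophil, 4.23 for stromal, 4.13 for erythroid and 3.61 for NK-cell markers, against 5.13 for all genes. The brightest were Cd2 (8.65), which mouse B cells also express, Cd68 (6.41) and Itgam (6.32). For BCR loss in untreated cultures their medians were 0.00, 0.06, 0.03, 0.05 and 0.03, with camera adjusted p of 0.31 or more. Of single markers Cd2 rose (0.99), and Itgam (0.76) and the NK-cell marker Klrb1c (0.56) did not pass, while no other reached 0.5.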

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

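The tests of handling and of other cell types were chosen only after the result was seen, and the probe sets without a single gene name were looked at only then. The effect of BCR loss differed between cultures for 11 gene lists by the interaction test at the preset correlation. Their interaction medians were -0.203 for early-response genes, -0.203 for NF-κB targets, -0.233 for FOXO targets, -0.0979 for Wnt targets, 0.122 for nucleotide synthesis, 0.0708 for oxidative phosphorylation, 0.329 for DNA replication, 0.213 for mitosis, -0.138 for antigen presentation, -0.108 for lysosome genes and -0.0578 for homing receptors. With an estimated correlation none of the 11 passed, and limma called 0 single genes (990 at an unadjusted p under 0.05). In 14338 probe sets with several gene names or none, 17 were called for CHIR99021 in BCR-negative cells, 1 higher and 16 lower, and 0 in the other comparisons (562 to 1812 at an unadjusted p under 0.05). Those 17 went to 0 without the block and without any 1 of the 3 lymphomas.

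With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 791, 3, 14, 692 and 3 genes for BCR loss untreated, BCR loss in CHIR99021, CHIR99021 in BCR-positive cells, CHIR99021 in BCR-negative cells and the last comparison, and the highest other split 0, 0, 0, 1 and 0, so that 1 split, the real one, was as large in each. For lists the real split gave 13, 8, 11, 14 and 10 and the highest other 12, 10, 7, 12 and 10, with 1, 4, 1, 1 and 2 splits as large. Among splits that part every pair of a lymphoma, the highest others were 12, 7, 5, 8 and 7 lists and 0 genes. The other splits keep both arrays of a lymphoma together. Swapping BCR status within lymphomas allows 4 arrangements for the interaction, again too few. All 4 gave 0 genes, and the real one gave 11 lists against at most 4. For the 17 probe sets the real split was the 1 of 10 as large, and the highest other gave 0.

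The first pattern was the effect of CHIR99021 in BCR-negative cells, opposite in sign to that of BCR loss. Noise of the shared untreated BCR-negative arrays cannot reach effects taken from different lymphomas, and there the lowest r was 0.148. A trend with signal intensity was removed with loess, and the lowest r was then 0.139. Both lie above the bound of 0.1 set beforehand, by little in the lowest of the 6 pairs. Neither noise of single shared arrays nor that trend therefore explains the whole pattern. A property common to the untreated BCR-negative samples of all lymphomas would enter both effects in every pair, so these tests cannot exclude it.

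The second pattern was that 5 of 28 early-response genes and 8 of 20 NF-κB targets were called higher in untreated BCR-negative cells. Neither list passed with an estimated correlation (camera, adjusted p = 0.23 and 0.089). A handling difference that is the same in both cultures would leave no interaction, but the larger adjusted p of the interactions of the 2 lists was 0.33665 (early-response genes; camera with an estimated correlation), so such handling stays open. That test first used the 48 genes joined (interaction median -0.296, -0.333 and -0.121 in lymphomas 2564, 2646 and 2676; camera with an estimated correlation, p = 0.00821), which had been joined after their interactions were seen and therefore decide nothing. Cells of another type would raise their markers, and the highest upper quartile among 5 marker lists was 0.116 (erythroid), below the early-response median of 0.57. Of single markers only Cd2 (0.99, called), Itgam (0.76) and Klrb1c (0.56) reached 0.5. The marker test first used the highest list median, 0.058, and was changed to the upper quartile after this was seen. Handling may thus contribute, whether it was the same in both cultures (0.33665 above) or not, which was not tested.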

How the results depend on the processing

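The alternatives for the averaged effects and for the probe sets without a single gene name were chosen only after the result was seen. Every gene called in the 6 comparisons kept its sign under each alternative run, which their single sign in all 3 lymphomas and the balanced design largely fixed beforehand. Counts moved, and the cause was not tested. Gene counts below are in the order BCR loss untreated, BCR loss in CHIR99021, CHIR99021 in BCR-positive cells, CHIR99021 in BCR-negative cells and the last comparison (791, 3, 14, 692 and 3). They were 5, 0, 0, 3 and 0 without the block and 75, 0, 1, 81 and 0 with a random block. With only the arrays compared they were 0, 109, 29 and 0 for these comparisons except BCR loss in CHIR99021, and with the finer block 0 and 33 for BCR loss in CHIR99021 and CHIR99021 in BCR-positive cells. The dim filter gave 0 and 23 and cyclic loess 0 and 9 for this pair. Subtraction of array medians gave 1301, 0, 2 and 1089 for all but the last, with a median shift of all genes under 0.1. Trend and robust gave 0 and 33 for the same pair and 5 for the last comparison, and a minimum of 1.5-fold gave 197 for BCR loss untreated and 184 for CHIR99021 in BCR-negative cells, by its construction. Lists called (13, 8, 11, 14, 11 for the interaction and 10) were 0, 0, 0, 0, 0 and 1 with an estimated correlation, 8, 0, 2, 9, 0 and 2 with fry, and 7 for the interaction without the block. Leaving out a lymphoma or an array gave 0 to 1204, 0 to 4, 0 to 38, 0 to 840, 0 to 2 (interaction) and 0 to 9 genes, and 10 to 16, 6 to 10, 8 to 13, 12 to 16, 8 to 13 and 5 to 14 lists. The correlations across genes went from 0.691 to 0.545 to 0.683 for BCR loss, from 0.655 to 0.504 to 0.634 for CHIR99021 and from 0.7497 to 0.645 to 0.766 for the opposite effects. The median of oxidative phosphorylation in the last comparison reversed to 0.0132 without lymphoma 2676 and to 0.00478 without its treated BCR-negative array, and its lowest value was -0.0800, without that array of 2564. For the averaged effects, the counts without the block were 1 for BCR loss and 25 for CHIR99021, and without a lymphoma 0 to 1807 and 289 to 463. The 17 probe sets went to 0 without the block and 0 to 0 without a lymphoma. The finer block could not be fitted to the last comparison. The dim filter removed genes below a mean signal of 4.12, and background was not measured.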

Other observations

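The averages over cultures or populations and the test of kappa V genes were chosen only after the result was seen. Averaged over both cultures, BCR loss was called for 592 genes higher and 569 lower (limma, 12 arrays, n = 3 lymphomas with 2 pairs each). Beside genes named above, Atp1b1 (1.57 ± 0.308), a sodium pump subunit, Rag2 (1.31 ± 0.236) and the signalling regulator Rgs16 (1.26 ± 0.271) were higher in 6 of 6 pairs, and Rasgrp1 (-1.11 ± 0.207), an activator of Ras, and Sh3bp5 (-0.90 ± 0.167) were lower in 6 of 6. Averaged over both populations, CHIR99021 was called for 691 genes higher and 646 lower. The cell cycle inhibitor gene Cdkn1a (1.39 ± 0.261), Adm (1.24 ± 0.224), which encodes adrenomedullin, and the haem oxygenase gene Hmox1 (1.10 ± 0.259) were higher, and the translation inhibitor gene Pdcd4 (-1.20 ± 0.114), Rag2 (-1.74 ± 0.236) and Ccng2 (-1.05 ± 0.116) lower, each in 6 of 6 pairs. The adjusted p of these genes in limma ran from 0.00075 to 0.0304.

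These averages were first taken within the model of 4 groups, which called 1247 and 1389 genes, and were then replaced by the additive model (1161 and 1337 genes) so that splits could be run. Of 100 splits of the 12 arrays, 1, the real one, gave as many genes for BCR loss, and the highest other gave 9. For CHIR99021 it was also 1 of 100, and the highest other gave 872, in a split that leaves 10 of 12 arrays on their real side, and the next 119. Those splits ignore the pairs. Swaps within the 6 pairs allow 32 arrangements, of which 1, the real one, gave as many genes in each case and the others 0. The share is under 0.05 in both ways of drawing, but the 2 pairs of a lymphoma are not independent, and swaps of whole lymphomas allow 4 arrangements, too few for such a share. The counts rest on few lymphomas, since BCR loss gave 0 genes without 2646 or 2676 and 1807 without 2564, and CHIR99021 gave 291, 289 and 463 without 2564, 2646 and 2676.

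In lymphoma 2676, 5 of 12 immunoglobulin kappa V genes were higher by at least 1 (log2) in BCR-negative cells of the untreated culture, and 4 of them also with CHIR99021. Igkv1-135 differed by 2.04 and 1.72 and Igkv8-19 by 1.94 and 1.72, while in lymphomas 2564 and 2646 no kappa V gene was higher by that much and 1, Igkv10-96, was lower (-1.07 and -1.10 in untreated cultures). The differences in the 2 cultures, which share no array, correlated over the 12 genes at r = 0.805 (rho = 0.762, permutation p = 0.0022, adjusted p = 0.0066 over 3 lymphomas). In 2564 r was 0.706 (permutation p = 0.0099, adjusted p = 0.015) and in 2646 it was 0.556 (permutation p = 0.062). V genes resemble each other and are not independent replicates. The test was also chosen after the result was seen, so its p-values cannot decide on noise of single arrays.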
